A study of Mus musculus with 4 samples.

How the data were processed

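Total RNA from 4 subclones of the mouse hybridoma 36-65, grown with 10% fetal calf serum, was labelled with biotin and hybridized to 1 Affymetrix expression array for each subclone, per the labels. Low switching replicates 1 and 2 are subclones L25 and L27, and high switching replicates 1 and 2 are subclones H23 and H27. The deposited values are intensities on a linear scale, and the submitters' processing notes name RMA (robust multi-array average, which corrects background, normalizes between arrays and summarizes probes) without a version. RMA shrinks differences of dim probe sets, so folds of genes near the lower end of the range may be understated. Values had been assumed to be log2 when the tests were chosen. They were found to be linear, with medians from 38.1 to 39.3 and maxima near 38852, and were transformed to log2 first.

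Of 45101 probe sets, 64 controls were left out and 45037 were tested with no filter on level. The platform annotation of 2016 gave 1 gene symbol for 34945 of them, several for 932 and none for 9160, and 34742 of those with 1 symbol matched a gene table of assembly GRCm38.p6, which changed 1 symbol. The authors' genome build is not given in the sources used here, so the table served only for names, chromosomes and the order of neighbouring genes, and no coordinates are given. Probe sets with several symbols or none were tested and not named. Some genes that were to be named whatever their value are not reported here.

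High minus low switching was tested for each probe set with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The SE is the moderated standard error, and intervals are at 95%. For lists, the probe set with the highest mean over the 4 arrays stood for its gene (18193 genes), and 23 lists were tested with camera (preset correlation 0.01), with camera and a correlation estimated for each list, and with fry, each adjusted over the lists. The lists, tests, alternatives and rule for named genes were fixed before the data were examined. The rule took the 15 genes with the largest rise and the 15 with the largest fall among probe sets past the threshold with 1 symbol and a brighter group mean of at least 7 (log2), up to 4 members of each list past the threshold over all probe sets or over the list alone, and a fixed set of genes of switching and plasma cells. For the order along chromosomes, genes with a mean of at least 7 were put into bins of 20 and compared with 1000 shuffled orders. These bins and the stretches named from them were chosen after seeing the data.

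The steps were tested on simulated data with the size and spread of the comparison (10 draws, 200 changed probe sets in each, 45037 probe sets). The test recovered 0.6% of changes of 0.5, 40.6% of changes of 1, 97% of changes of 2 and 100% of changes of 4 (log2), and 6.07% of its calls were false. Changed probe sets were drawn from those with a mean log2 intensity of at least 7. Spreads were drawn from the variance distribution that limma fitted, with normal noise, so the share of false calls was largely set by the simulation. Only 200 probe sets were changed in each draw, against 1618 called in the data, so recovery in the data may differ. With no change simulated, 0 of 23 lists passed, and a simulated shift of 0.5 in the interferon list was found (18193 genes). Probe sets were simulated as independent of each other, so this does not show how the list tests behave where genes shift together. In this simulation, small differences were mostly missed with 2 arrays for each class.

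Alternatives were a variance trend, with and without robust estimation, filters on dim probe sets, other normalizations, leaving out probe sets that may match more than 1 transcript (names ending in _x_at, _s_at or _a_at), 1 probe set for each gene, a minimum fold of 1.5, and leaving out each array. Hybridization controls had mean log2 intensities of 10.95 and 10.84 on low switching replicate 1 and high switching replicate 2, and 10.37 and 10.40 on low switching replicate 2 and high switching replicate 1. This level crosses the classes, and was added as a block after seeing the data, as was the subtraction of the median of neighbouring genes (20 on each side). The 3′ minus 5′ difference of actin controls was between 0.22 and 0.33. Arrays were otherwise given no batch in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.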

Results

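Gene expression was measured in subclones of the mouse hybridoma 36-65, an antibody-secreting line made by fusing a B cell with a myeloma cell. Antibody-producing cells can exchange the constant region of their heavy chain, a process called class switching. The labels divide the subclones by how often they did so in culture, and call only the high frequencies spontaneous. There were 2 subclones with low and 2 with high switching frequency, with 1 array of total RNA for each. The median probe set had an intensity between 38.1 and 39.3 on the 4 arrays, and the number of arrays limits the precision of every value below. Nothing in the labels says whether subclones of a class arose separately from each other, so p-values measure only the spread between these 4 subclones.

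The comparison of high with low switching subclones asked which transcripts differ between cells of the 2 switching classes. The genes Crip1 and Crip2, which encode small LIM-domain proteins, were among the most different. Crip1 had a mean log2 intensity of 14.87 ± 0.08 (SD, n = 2) in high switching subclones and 8.80 ± 0.59 in low switching subclones, a 67.5-fold difference, and Crip2 was 41.2-fold higher in high switching subclones (12.32 ± 0.44 against 6.96 ± 0.09). The high switching level of Crip1 is near the top of the range, with 12 of 45037 probe sets brighter there, so saturation is not excluded and its fold is approximate. Both genes lie beside the immunoglobulin heavy chain locus on chromosome 12. In the other direction, the kinase gene Rps6ka6 had a mean of 3.80 ± 0.14 in high and 9.71 ± 0.04 in low switching subclones, ceruloplasmin (Cp) 3.67 ± 0.00 against 9.55 ± 0.07, and Syce1, a gene of the meiotic synaptonemal complex, 4.08 ± 0.20 against 9.83 ± 0.16. The log2 differences of these 3 genes were -5.91 ± 0.12 (SE), -5.88 ± 0.11 and -5.75 ± 0.15, with limma adjusted p-values of 5.00e-05, 4.32e-05 and 7.05e-05.

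Other genes that rose in high switching subclones were Cnn3 (calponin, log2 difference 5.78), Mfsd1 (4.19), Pfn2 (profilin, 3.99), Fxr1 (an RNA-binding protein, 3.80), Plxnc1 (a semaphorin receptor, 2.89), Cd48 (2.81), Ptpn6 (the phosphatase SHP-1, 2.73), Lgals1 (galectin-1, 2.70), Rap1gds1 (2.64) and Fndc3b (2.62). Cacna1e, a calcium channel subunit, was 7.99-fold higher, and Golim4 had a mean of 7.31 against 4.31. Genes that fell were Trim30a (interferon-inducible, -5.32), Fhit (-4.62), Nbea (-4.62), Cttn (cortactin, -4.55), Ifi209 (-4.51), Sertad4 (-4.18), Pgam2 (-3.95), Nxf3 (-3.85), Cyb561a3 (-3.69), Zfp982 (-3.69), Iglv1 (a lambda light chain variable gene, -3.60) and Slc25a24 (a mitochondrial carrier, -3.58). In the class where they were dimmer, 7 of the 15 genes with the largest rise and 12 of the 15 with the largest fall, among them Rps6ka6, Cp and Syce1, lay below the median probe set of every array, where intensity need not track the amount of transcript, so the sizes and order of these differences are approximate. The SE of these log2 differences ranged from 0.10 for Rap1gds1 to 0.52 for Pgam2. Chromosome 3 carries 8 of the 15 genes with the largest rise and 3 of the 15 with the largest fall.

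Probe sets of a gene did not always show the same size of difference. Phgdh, the first enzyme of serine synthesis, had the largest difference of any named gene on a single probe set (6.34), while its other probe sets gave 0.34, 0.36 and 0.48 and did not pass the threshold. Golim4, Rap1gds1 and Ptpn6 also passed on 1 of 2 probe sets, as did Ifi209, whose second probe set differed by 0.03. Zfp982 and Iglv1 passed on 1 of 3 probe sets, and the other Iglv1 probe sets gave -0.15 and -2.82. By contrast, 7 of 8 Cp probe sets, 5 of 6 Cnn3 probe sets and all 3 Mfsd1 and Pfn2 probe sets passed in the same direction.

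**Figure D1:**
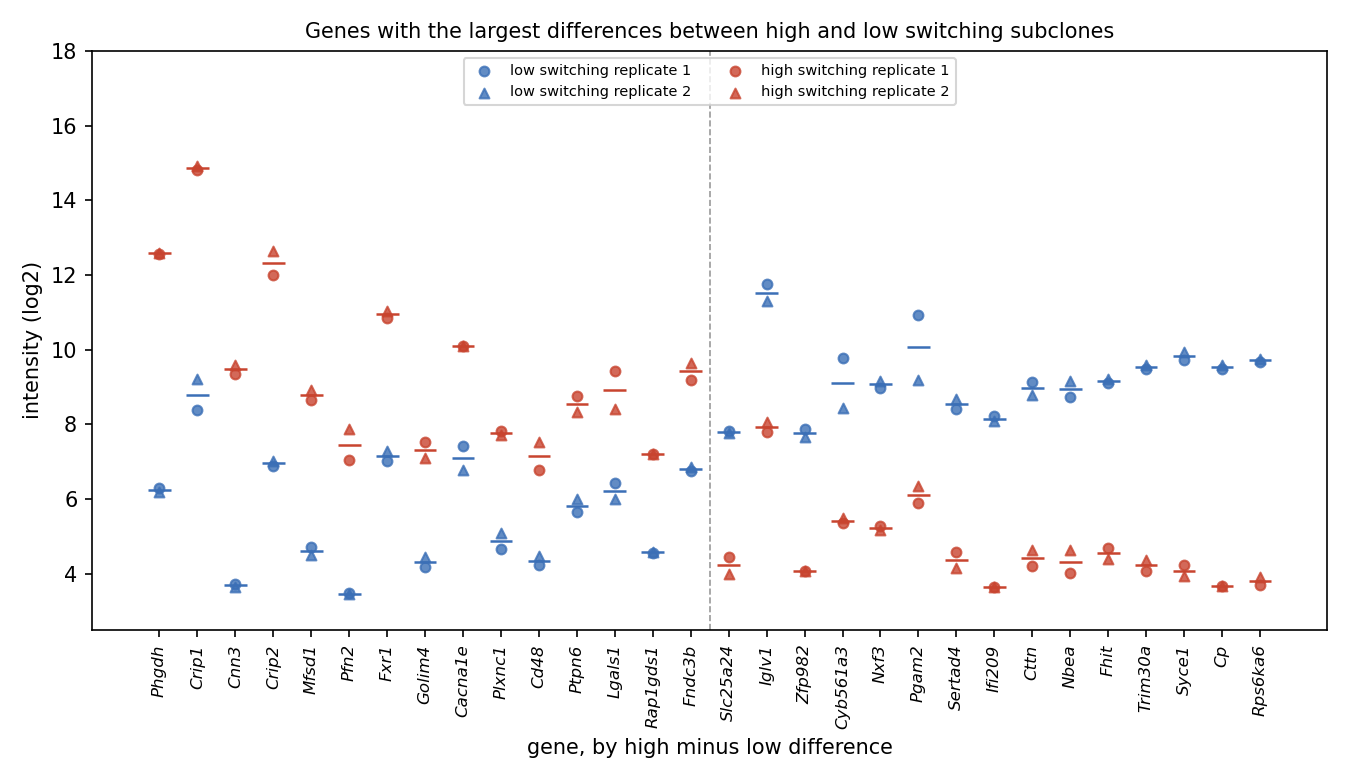
Log2 intensity on each of the 4 arrays (vertical axis) for the 15 genes with the largest rise and the 15 with the largest fall in high switching subclones (horizontal axis), blue for low and red for high switching, with short lines at the mean of 2 arrays. For each gene the 2 high switching arrays lie apart from the 2 low switching arrays, as for Crip1 (14.87 against 8.80).

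In all, 674 probe sets (457 genes) were higher and 944 (664 genes) lower in high switching subclones, which is 3.59% of the 45037 probe sets tested with limma at an adjusted p under 0.05. Differences of at least 16-fold were found for 8 probe sets that rose and 15 that fell. A rule with no variance model, which asks that each high switching array lie at least 2-fold from each low switching array, held for 154 probe sets in the higher and 258 in the lower direction. Between the subclones of a class, 133 probe sets differed 2-fold in the low switching pair and 109 in the high switching pair, against 904 to 1138 between subclones of different classes. With the level of the hybridization controls as a block, an alternative chosen after seeing the data that leaves fewer degrees of freedom, 58 were higher and 94 lower. When 1 array was left out, the count fell to 112 higher and 196 lower without low switching replicate 1, 220 and 272 without low switching replicate 2, 196 and 304 without high switching replicate 1, and 253 and 329 without high switching replicate 2. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333, so the calls rest on the variance that limma shares across probe sets.

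Interferon response genes were lower in high switching subclones. Of 31 measured members, 11 fell and 0 rose (15 and 1 adjusted over the list alone), with a median log2 difference of -0.44. The other 20 did not pass over all probe sets, among them the transcription factors Irf7 (-0.66 ± 0.24, SE), Irf9 (-0.09 ± 0.22) and Stat2 (-0.08 ± 0.18). The largest falls were in Trim30a (-4.55 on the probe set that stands for the gene), Xaf1 (-2.53 ± 0.11, SE), Lgals3bp (-2.33 ± 0.28) and Usp18 (-2.26 ± 0.12), the last a brake on interferon receptor signalling. Ifnar2, a subunit of the type I interferon receptor, fell by 1.96 on the log2 scale, and all 3 of its probe sets passed. The list passed limma's camera test with a preset correlation (adjusted p = 3.55e-09), and not with an estimated correlation (adjusted p = 0.42). The fry test gave an adjusted p of 0.0184.

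Genes of the unfolded protein response, which adjusts the endoplasmic reticulum to its secretory load, were higher. Of 27 members, 5 rose and 0 fell (8 and 1 adjusted over the list alone), with a median difference of 0.19. They were the transcription factor Ddit3 (CHOP, 1.47 ± 0.13), Trib3 (0.94 ± 0.12), Herpud1 (0.83 ± 0.13), Chac1 (0.65 ± 0.12) and the chaperone calreticulin (Calr, 0.62 ± 0.12). Xbp1, a transcription factor of the same response and of plasma cells, had a difference of -0.71 ± 0.13 (adjusted p = 0.0461), and 3 of its 4 probe sets fell. The list passed with the preset correlation (adjusted p = 0.00216) and by fry (adjusted p = 0.0184), but not with an estimated correlation (adjusted p = 0.66). When any single array was left out, the calls of Trib3, Herpud1, Chac1, Calr and Xbp1 ended, and that of Ddit3 held.

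Factors of class switching and somatic hypermutation were lower as a list. Of 30 members, 5 fell and 0 rose (7 and 3 adjusted over the list alone), with a median difference of -0.17. The members that fell were Nbn, a DNA break sensor (-0.95 ± 0.11), the histone variant H2ax (-0.85 ± 0.16), the endonuclease Apex1 (-0.70 ± 0.12), the ubiquitin ligase Rnf168 (-0.68) and the uracil glycosylase Ung (-0.64 ± 0.11, adjusted p = 0.0362). The glycosylase Mbd4 had a difference of 0.83 and an adjusted p of 0.0751 on the probe set that stands for the gene, and 1 of its 3 probe sets passed as higher (0.94, adjusted p = 0.04). The list had an adjusted p of 0.0133 with the preset correlation, an adjusted p of 0.75 with an estimated correlation and an adjusted p of 0.235 by fry. Its call also ended with dim probe sets left out (adjusted p = 0.086), with quantile normalization applied again (0.0512), with cyclic loess (0.0514) and, an alternative chosen after seeing the data, with the median of neighbouring genes subtracted (0.142, median -0.10). Without high switching replicate 2 its median was -0.07 (adjusted p = 0.218) and without high switching replicate 1 it was -0.29 (0.00177). When any single array was left out, the calls of Nbn, H2ax, Apex1, Rnf168 and Ung all ended.

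Lists of DNA replication genes and of homologous recombination and checkpoint genes were also lower, with median differences of -0.39 over 36 members and -0.21 over 27 members. Among the replication genes only Rfc3, a subunit of the clamp loader, fell over all probe sets tested (-1.07 ± 0.18), and 4 fell adjusted over the list alone, among them Pole (-0.53) and Pold1 (-0.53). Among the recombination genes the kinase gene Chek2 (-0.69 ± 0.12) and Rad54l (-0.62 ± 0.11) fell, and 3 fell adjusted over the list alone. The high switching subclones also differed from each other, with medians of -0.32 for the replication list and -0.19 for the recombination list, replicate 2 against replicate 1. The preset correlation gave adjusted p-values of 0.000618 and 0.0014, and both had an adjusted p of 0.75 with an estimated correlation; fry gave adjusted p-values of 0.413 and 0.302. Without high switching replicate 2, both had an adjusted p of 0.0871, and the median of the replication list was -0.21. The calls of Chek2 and Rad54l ended when any single array was left out. Rfc3, Pole and Chek2 lie on chromosome 5, where genes with a mean of at least 7 had a median difference of -0.31. Pold1 and Rad54l lie on chromosomes 7 and 4, where it was -0.18 and -0.13. Both lists still passed with the preset correlation after the median of neighbouring genes was subtracted, an alternative chosen after seeing the data.

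Target genes of the p53 tumour suppressor were higher, with 4 of 26 members rising and 1 falling (8 and 2 adjusted over the list alone) and a median difference of 0.15. The cell cycle inhibitor Cdkn1a (1.60 ± 0.24) and Gadd45a (1.18 ± 0.12) rose, as did Ei24 (0.89) and Sesn1 (0.82), while the pro-apoptotic gene Pmaip1 fell (-0.92 ± 0.16). The list had an adjusted p of 0.0205 with the preset correlation, an adjusted p of 0.69 with an estimated correlation and an adjusted p of 0.0785 by fry. It did not pass without low switching replicate 1 (adjusted p = 0.0562), without high switching replicate 2 (0.0735) or, an alternative chosen after seeing the data, with the median of neighbouring genes subtracted (0.0511), and its median was 0.24 without high switching replicate 1. The calls of Ei24 and Pmaip1 ended when any single array was left out. Those of Cdkn1a (1.26 to 1.93), Sesn1 (0.643 to 1.005) and Gadd45a (1.09 to 1.27) ended without some arrays.

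The other 17 lists did not pass camera, but single members did, and the chromatin list passed fry. Among 36 B cell genes, Cd40 (1.68), Bcl6 (1.44) and the receptor subunit Cd79b (0.77) rose, and Bank1, a B cell scaffold protein (-3.24), and Swap70 (-1.01) fell; 5 rose and 4 fell adjusted over the list alone. Among 28 plasma cell genes, Fndc3b rose, and Xbp1 and Tnfrsf17, the receptor BCMA (-0.72), fell, with 2 rising and 9 falling adjusted over the list alone. Among 36 genes listed as regulators of switching, Id1, an inhibitor of E-protein transcription factors (-1.56), and the ubiquitin ligase Stub1 (-0.93) fell, with 8 falling and 4 rising adjusted over the list alone. Among 38 cytokine receptors and signals that induce switching, Tlr4 (-1.97), Ifnar2 and Smad7 (-1.02) fell, and Cd40 and Il6st (0.99) rose (6 and 3 adjusted over the list alone). When any single array was left out, the calls of Cd79b, Swap70, Xbp1, Tnfrsf17, Stub1 and Il6st ended. Those of Cd40, Id1, Tlr4 and Smad7 ended without some arrays, and those of Bcl6, Bank1, Fndc3b and Ifnar2 held. The class II gene H2-Ob rose (1.30), from 3.88 in low to 5.17 in high switching subclones. Both means lay below the median probe set of every array, so the size of this difference is approximate. Cd74, the invariant chain, had a difference of -2.20 with a limma adjusted p of 0.115. The high switching arrays read 7.72 and 9.75 for Cd74, and its difference was -3.22 without high switching replicate 2, where it passed (adjusted p = 0.00371), and -1.19 without high switching replicate 1 (0.0555).

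Among 22 stress and RNA quality genes, Jun fell (-1.85) while Fos (1.01), Junb (1.01), Hmox1 (0.97), Srxn1 (0.90) and Ier2 (0.90) rose, and 8 rose and 1 fell adjusted over the list alone. This list had an adjusted p of 0.102 with the preset correlation, of 0.752 with an estimated correlation and of 0.0898 by fry, and its median of 0.08 was 0.17 without low switching replicate 2 and 0.19 without high switching replicate 2. With the preset correlation it passed with a mean of at least 6 (0.0302), with a mean above the median probe set (0.0388), without probe sets that may match more than 1 transcript (0.0235) and with the mean over the probe sets of a gene (0.0454). Of the chromatin genes, the DNA methyltransferase Dnmt3a fell (-1.07) and the remodelling ATPase Smarca4 rose (0.82); the list had a median of -0.06 and an adjusted p of 0.741 by camera with the preset correlation, of 0.786 with an estimated correlation and of 0.0256 by fry. Its median was -0.13 without high switching replicate 1, 0.02 without high switching replicate 2 and, an alternative chosen after seeing the data, 0.04 with the median of neighbouring genes subtracted, so the direction of this list is not settled. The NF-kappaB targets that rose were Icam1 (1.31), Birc2 (1.10) and Cd40, and the sterol genes that rose were Msmo1 (0.91) and Srebf2 (0.66). Of the apoptosis regulators, Casp12 (-1.26), Pmaip1 and Bcl2l1 (-0.82) fell and Birc2 rose. Among 28 glycolysis and hypoxia genes and 32 genes of the G2 and M phases, limma called 0 at the adjusted threshold, over all probe sets and adjusted over the list alone, while 8 and 7 had an unadjusted p under 0.05. Adjusted over the list alone, 3 class II genes rose and 6 fell, as did 1 and 2 chromatin genes, 3 and 0 NF-kappaB targets, 3 and 0 sterol genes, and 6 and 3 apoptosis regulators. Calr, Rnf168, Ei24, Sesn1, Cd79b, Swap70, Tnfrsf17, Il6st, Srxn1, Ier2, Bcl2l1, Irf7, Irf9 and Stat2 are named beyond the fixed rule and were chosen after their values were seen.

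Few markers of other cell types passed. Of T cell markers 0 of 21 passed, of erythroid markers 0 of 11 (2 of each list at an unadjusted p under 0.05 by limma), of myeloid markers 1 of 24 (Itgam, -1.38) and of fibroblast markers 1 of 19 (Lum, 1.21). Adjusted over the list alone, these counts were 0, 1, 3 and 1. The median level of the members was 5.61, 4.51, 4.70 and 5.03 (log2), in the same order, near or below the median probe set. Of all probe sets 3.59% passed, so these counts say little about other cell types. Lum had means of 4.32 in low and 5.53 in high switching subclones. Immunoglobulin genes had 1 of 19 genes past the threshold at the gene level, a kappa light chain variable gene (-0.70). Its means of 5.77 in low and 5.07 in high switching subclones were near the median probe set. Iglv1 did not pass there, since the probe set with the highest mean stands for it (-2.82, limma adjusted p = 0.284). Another of its probe sets passed (-3.60, limma adjusted p = 0.000977). The camera direction, the median and the mean did not all have the same sign for the lists of B cell genes, genes of the G2 and M phases, NF-kappaB targets, glycolysis genes, myeloid markers, erythroid markers and immunoglobulin genes, none of which passed.

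Genes central to plasma cells and to switching were named whatever their value. Bcl6, a repressor of plasma cell differentiation, rose by 1.44 ± 0.12 (adjusted p = 0.00587), and both of its probe sets passed. The plasma cell factors Prdm1 (0.74 ± 0.20, adjusted p = 0.119) and Irf4 (0.03 ± 0.14, 0.955) and the plasma cell surface marker Sdc1 (0.11 ± 0.12, 0.708) did not pass. Neither did the mismatch repair gene Msh6 (-0.16 ± 0.11, adjusted p = 0.537), Id2 (-0.78 ± 0.23, 0.148) or Id3 (0.60 ± 0.15, 0.0982). The difference of Id2 was -1.14 without high switching replicate 1, where it passed (adjusted p = 0.0359), and -0.41 without high switching replicate 2. Pax5, the B cell identity factor, differed by 0.00 with a 95% interval from -0.37 to 0.38. Its mean log2 intensity was 5.37 in each class, near the median probe set, where a difference need not show. When 1 array was left out, Prdm1 ranged from 0.46 to 1.03, Irf4 from -0.14 to 0.20, Sdc1 from 0.02 to 0.20, Msh6 from -0.22 to -0.10, Id3 from 0.41 to 0.78 and Pax5 from -0.18 to 0.18, and none of these 6 passed.

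Whole chromosomes and parts of them shifted together between the classes. Genes with a mean log2 intensity of at least 7 had a median difference of 0.37 on chromosome 3, where 91.6% of 370 genes were higher, and of 0.24 on chromosome 8. On chromosomes 5 and 16 the medians were -0.31 and -0.27. Some chromosomes were split: the first 100 such genes of chromosome 9, from Alkbh8 to Hspa8, had a median of 0.48 and the rest -0.08, and on chromosome 12 the stretch from Rab10 to Egln3 had -0.39 and the rest 0.24. Subclones of the same class differed in the same way, with a median of -0.33 between the low switching subclones from Scaf8 to Rab5a on chromosome 17, and of 0.25 (low) and 0.18 (high) for replicate 2 against replicate 1 on chromosome 3.

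The medians of 400 bins of 20 neighbouring genes had an SD of 0.222 for high against low switching, where shuffled gene orders gave a mean SD of 0.0937. The SD was 0.11 between the low switching subclones (shuffled 0.0476) and 0.127 between the high switching subclones (shuffled 0.0597). In each case the one-sided permutation p was 0.001, the smallest that 1000 shuffles can give. With a set test for each chromosome, 13 passed with the preset correlation and 0 with an estimated correlation, for which the lowest adjusted p was 0.159. Ung lies on chromosome 5, and with the median of its neighbours subtracted its difference was -0.43 (adjusted p = 0.0765), an alternative chosen after seeing the data.

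**Figure D2:**
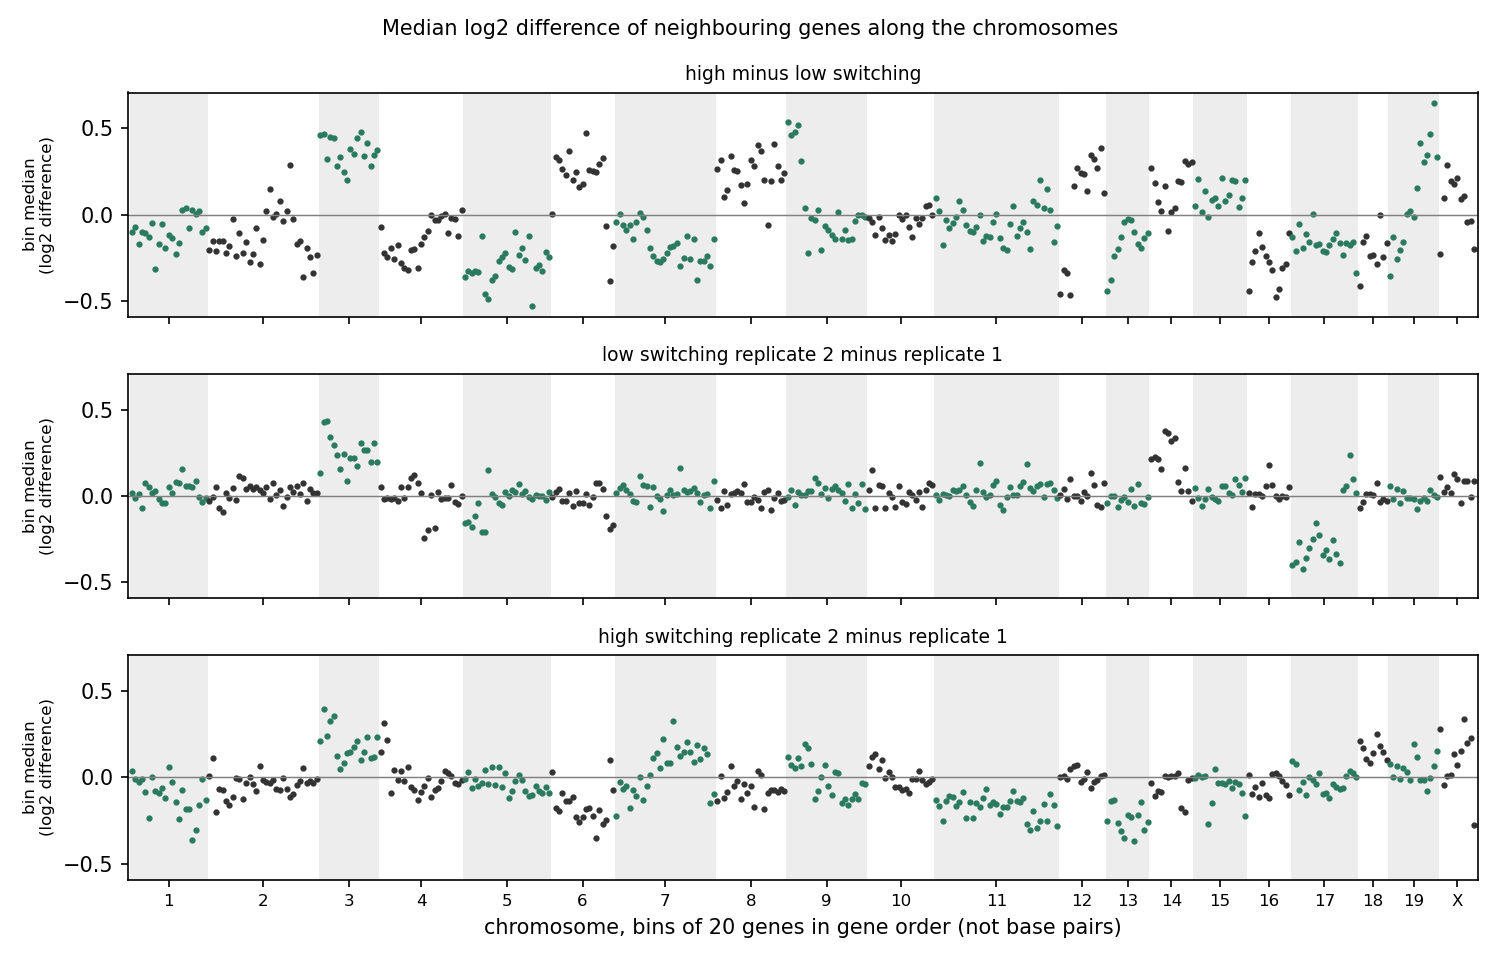
Median log2 difference (vertical axis) of bins of 20 neighbouring genes in gene order along chromosomes 1 to 19 and X (horizontal axis), for high minus low switching and for replicate 2 minus replicate 1 within each class; each point is 1 bin. Bins of chromosome 3 lie above 0 in all panels, and the stretch from Scaf8 to Rab5a on chromosome 17 lies below 0 between the low switching subclones (median -0.33).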

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

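Subtracting the median of neighbouring genes and using the control level as a block were chosen after seeing the data; the other alternatives were planned. Under each alternative that was run, 0 probe sets called in the analysis as reported were called in the opposite direction. For all 1618 called probe sets, every high switching array lay beyond every low switching array. Leaving out an array or adding the block thus could not turn a call, and kept directions there are no separate evidence. The counts of 674 higher and 944 lower probe sets stayed within 1.5 times under the variance models, filters and normalizations. They became 59 and 104 with a minimum fold of 1.5, 58 and 94 with the hybridization control level as a block (which leaves fewer degrees of freedom), and 112 to 253 and 196 to 329 when 1 array was left out (fewer samples, where the lone array is assumed to vary like the pair of the other class). With the median of neighbours subtracted, on 1 probe set for each gene, 552 were higher and 496 lower (52.7% higher, against 41.7% as reported), of which 239 and 330 were among the calls as reported. With 1 probe set for each gene and no subtraction, 506 were higher and 658 lower, of which 372 and 505 were among them. Of 123 named probe sets, 39 to 51 lost their call when 1 array was left out, 60 with a minimum fold of 1.5 and 61 with the control level as a block, all keeping their direction. The 412 probe sets that met the 2-fold size rule became 1342 at 1.5-fold, 94 at 4-fold, 238 with 1 probe set for each gene and 561 to 722 when 1 array was left out, all by construction. The 242 probe sets that differed 2-fold within a class were 174 with a mean of at least 6 and 249 after quantile normalization. Against 6 lists past the threshold as reported, 0 passed with an estimated correlation, 3 with fry (interferon response, unfolded protein response and the chromatin list, which is not among the 6), 4 with the median of neighbours subtracted (class switch factors 0.142 and p53 targets 0.0511 ended) and 2 to 6 when 1 array was left out, with 2 without high switching replicate 2. The 13 chromosomes became 0 with an estimated correlation and 7 to 10 when 1 array was left out; the cause was not tested.

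Results that turned direction had not passed limma or camera in the analysis as reported, though the chromatin list had passed fry (0.0256). Pax5 became -0.0188 after quantile normalization, -0.0198 after median centring, -0.0426 after cyclic loess and -0.18 to 0.18 when 1 array was left out, Irf4 -0.14 to 0.20 when 1 array was left out, Ifngr2 -0.27 to 0.20 when 1 array was left out, and, with the median of neighbours subtracted, Msh6 0.17, Ifngr2 0.16 and Igha -0.0777. Lists turned with these adjusted p-values, and the cause was not tested. With a mean of at least 6 they were chromatin genes 0.908, glycolysis 0.981, T cell markers 0.908 and myeloid markers 0.734. With a mean above the median probe set they were glycolysis 0.963, T cell markers 0.963 and immunoglobulin genes 0.967. Without probe sets that may match more than 1 transcript they were regulators of switching 0.937, class II genes 0.495 and NF-kappaB targets 0.925, and after cyclic loess glycolysis 0.988. With the median of neighbours subtracted they were class II genes 0.915, switch-inducing signals 0.989, apoptosis regulators 0.941 and immunoglobulin genes 0.17. When 1 array was left out the ranges were 0.142 to 0.589 for genes of the G2 and M phases, 0.432 to 0.925 for NF-kappaB targets, 0.218 to 0.471 for glycolysis, 0.214 to 0.923 for T cell markers and 0.727 to 0.991 for erythroid markers. Trend and robust estimation together were not run for lists. No paired analysis was possible from the labels because they number the subclones without tying a low to a high switching one; the block above pairs arrays by their measured control level. Dim probe sets limit what can be seen: of the called probe sets, 114 of those that rose and 171 of those that fell lay below the median probe set in their lower class.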

Other observations

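The tests in this part were chosen after the results were seen, except that the shifts by expression level and the interferon list without each array were computed only after their predictions were written. The segments used for the shifts by expression level had been picked from the same data. Genes named below that are not in the report were picked after their values were seen. Of neighbours on chromosome 9, S1pr2, Mrpl4, Icam1 and Icam4 formed a run of 4 called genes, all higher with a median log2 difference of 1.36. Pcgf6, Taf5, Atp5md and Pdcd11 formed another on chromosome 19 (0.77). A run of 4 or more was found in 13 of 1000 shuffled orders. When any single array was left out, the calls of Mrpl4, Pcgf6, Taf5, Atp5md and Pdcd11 ended. Those of S1pr2 (1.84 to 3.12) and Icam1 (1.08 to 1.54) ended without some arrays, and that of Icam4 held (1.39 to 1.43). Beside Ifnar2, other receptor subunits on chromosome 16 differed unequally: Il10rb fell by 1.41 on its brighter probe set (limma adjusted p = 0.0111), the probe sets of Ifnar1 gave -0.85 (0.0518) and -0.59 (0.0475), and those of Ifngr2 gave -0.04 and -0.03. The brightest Ighm probe set had mean log2 intensities of 14.97 in low and 14.91 in high switching subclones, near the highest mean of any probe set (15.23), where a difference need not show. Some other Ighm probe sets were as dim as 4.27 in low and 4.34 in high switching subclones. The level of the Ighm transcript itself is thus not settled.

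Neighbouring genes shifted together along the chromosomes. Noise of single arrays is argued against by the bin medians of 2 pairs of arrays that share no array, which had a Pearson correlation of 0.777 across bins (bins are not independent replicates). A change of gene dosage over whole segments is a candidate explanation that these values do not test. On chromosome 3, the start of chromosomes 9 and 12 and the end of chromosome 19, genes of lower, middle and higher level shifted the same way. All had a mean of at least 7, and the medians shifted by at least 0.263. These segments were picked after seeing the data, and 91.6%, 94%, 13.75% and 89.2% of their genes, in that order, were higher. The same direction at each level was thus largely set by that choice, and is no evidence for or against dosage. Shifts of neighbouring genes need not follow the switching class, since within a class the SD of bin medians was at least 2.13 times that of shuffled orders. No DNA measurement and no probe sequences were used here, so copy number itself and base composition were not tested.

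On chromosome 12, the 5 measured genes directly before Igha, the last heavy chain constant gene, were all higher in high switching subclones: Mta1 (2.29), Crip2 (5.37), Crip1 (6.08), Tedc1 (1.29) and Tmem121 (0.84), while Igha (0.12) did not pass. A second Mta1 probe set, below the median probe set in both classes (4.76 and 4.67), differed by -0.09 (adjusted p = 0.751). The run of 5 calls rests on all 4 arrays: the call of Tmem121 ended without any 1 of them (0.73 to 0.95), that of Mta1 without low switching replicate 1 (1.94) or high switching replicate 1 (2.02), and that of Tedc1 without low switching replicate 1 (1.19), while Crip1 and Crip2 passed each time. A chance order of called genes is argued against, since a run of 5 or more was found in 1 of 1000 shuffled orders. A gain of the end of chromosome 12 as the whole cause is argued against for Crip2 and Crip1. Their 95% intervals started at 4.85 and 5.43, above the highest of 25 other genes there with a mean of at least 7 (1.15, median 0.12). That gene, Adssl1, had an interval up to 1.73. The interval of Mta1 started at 1.63, above 1.15 but below 1.73, so a gain stays open for Mta1. The 95% interval of Tedc1 started at 0.979, below the 1.15 of Adssl1, so this comparison leaves a gain open for Tedc1. With the median of neighbours subtracted, Tedc1 went from 1.29 ± 0.13 (SE) to 1.11 ± 0.14 and still passed (limma adjusted p = 0.00515). It thus lay above the median of its neighbours, which does not decide on a gain, since genes there differ from each other. Tmem121 went from 0.84 ± 0.13 to 0.64 ± 0.15 and its call ended (adjusted p = 0.0519, against 0.0266 with 1 probe set for each gene and no subtraction), since its difference was smaller and its SE larger; a gain stays open for Tmem121. Whether the run follows the switching class itself cannot be told apart from the history of the subclones, with 2 subclones for each class.

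Interferon response genes were lower in high switching subclones. Regional shifts of neighbouring genes are argued against as the whole cause, since the list's median was -0.41 with the median of neighbours subtracted (95% interval over resampled members -0.90 to -0.26, members taken as independent; adjusted p = 2.16e-09 with the preset and 0.41 with an estimated correlation). A single array is argued against, since the median stayed at -0.35 or lower without any 1 array and camera with the preset correlation still passed. A lower level of the interferon receptor, whose subunit Ifnar2 differed by -1.96, cannot be told apart from another shared cause without an experiment on the receptor, and the switching class stays open as well.

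Of the 3 splits of the 4 arrays into 2 against 2, 1 gave as many probe sets past the threshold, the real one with 1618; the highest of the others gave 0 with limma, with 546 and 891 at an unadjusted p under 0.05. The splits are too few for a share under 0.05.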
